A study of Arabidopsis thaliana with 9 samples.

How the data were processed

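The data were a table of probe set signals from 9 Affymetrix ATH1 arrays, hybridised with biotin-labelled RNA from whole plants and prepared with a 3' IVT Express kit, per the labels' protocols. The intensity values in the deposited table are linear MAS5 signals; MAS5 and GCOS are named per the submitters' processing notes, with versions not given in the sources used here. In each array the mean signal after trimming 2% at each end was 99.95 or 99.96, so the arrays had been scaled to a common level before deposit. Detection calls were not used here. Signals in the lowest range lie near background, where levels have little meaning.

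Groups and replicate numbers were taken from the sample titles. The table holds 22810 probe sets, of which 64 control sets were left out and 22746 tested. Signals were transformed as log2(signal + c) with c = 4.03, the 20th percentile of all values. Differences on this scale understate the change of probe sets near or below c. All 9 arrays entered one linear model in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. Lists and families were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. On simulated arrays with the spread of these, in the comparison of the null mutant with the double transformant over 22746 probe sets, 50% of 100 probe sets changed by 1 on the log2 scale and 91% of 100 changed by 2 were recovered, 7.24% of 152 calls were false, and 8% of 100 random lists passed camera at an unadjusted p of 0.05.

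Gene names came from an older platform annotation, updated through gene identifiers with the RefSeq annotation of TAIR10.1, which was used only for names and neighbour order. It gave 13513 probe sets 1 gene and 503 several, and 8794 probe sets are unnamed here; 13436 of the single-gene sets matched a current locus, and 13286 loci were represented, each by its probe set with the highest mean. HDA6, FLC, FWA and ROS1, which were to be reported in any case, were among the unnamed probe sets and are not analysed here. Of 22 lists fixed before the data were examined, 11 had at least 3 measured members and were tested. Those for transposable elements and ribosomal proteins were defined by words in gene descriptions. Only gene symbols and synonyms were searched for these words, which matched no gene, so neither list was tested. The remaining lists are given by single members. The salicylic acid and pathogen list had 0 measured members.

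Genes named were fixed by rule before the data were examined: in each mutant comparison the 10 largest rises and 10 largest falls among calls whose 3 arrays of one group all lay beyond those of the other, 5 and 5 between the mutants, and from each list up to 4 called members or, with none called, the 2 with the smallest p. Members of lists with too few genes to test, symbol families, the pseudogene class, the chromosome 5 run and the neighbourhood of raised genes were chosen after the data were seen. Where replicate numbers recur across groups, the deviations of same-numbered arrays correlated between -0.0409 and 0.154, so the numbers were not treated as pairs.

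Alternatives tried were other offsets, a filter on dim probe sets, quantile and median normalization, other variance priors, array weights, a replicate block, a block for the rpt titles, leaving out the rpt arrays or single arrays, fits of 6 arrays, stricter thresholds and an unmoderated test. An offset of 8c, leaving out double transformant 3 and null mutant 3 together, and plain probe sets only were added after the data were seen.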

Results

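RNA from whole Arabidopsis thaliana plants of the Col-0 strain was measured on 9 single-colour ATH1 arrays. Plants had grown for 35 days on Murashige and Skoog plates at 21 ºC in constant light. The arrays fell into 3 groups of 3: a double transformant of the Columbia background, whose labels name no HDA6 mutation, a null mutant of HDA6, and an HDA6 amino acid substitution mutant. HDA6 is a histone deacetylase that takes part in gene silencing. What the double transformant carries was not given in the sources used here, and it served as the reference group. The labels name rts1-1 as the source of both mutant groups, and only the titles tell a null mutant from a substitution, so whether these are separate alleles or lines was not settled by the labels. Night humidity was 35% for double transformant 1 and 53% for the other arrays. The median signal per array lay between 31.8 and 36.8, and the number of arrays limits the precision. Within groups, the correlation of log2 signals between arrays ran from 0.956 to 0.974 in the double transformant, from 0.945 to 0.963 in the null mutant and from 0.972 to 0.977 in the substitution group. Double transformant 3 and null mutant 3 had the lowest mean correlation with the other arrays (0.9458 and 0.9445), the lowest array weights (0.572 and 0.551) and the highest 3' to 5' signal ratios of the GAPDH control (2.15 and 1.95, against 1.38 to 1.82 in the others), while their ratios for the ubiquitin control (3.21 and 3.57) lay within the range of the others. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The probe set for HDA6 itself was unnamed here, so the level of the mutated gene was not analysed.

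The first comparison asked which transcripts differ when HDA6 is lost. In the null mutant, QQS, a gene of starch metabolism known for epigenetically variable expression, rose from a signal of 10.9 ± 1.5 to 991 ± 113 (SD, n = 3), a log2 difference of 6.06 ± 0.13 (SE, limma adjusted p = 3.24e-10). AT1G58025 rose by 6.12 ± 0.36 on the log2 scale (adjusted p = 5.49e-06) and AT2G15560 by 5.09 ± 0.16 (adjusted p = 1.01e-08). AT5G26270 rose by 4.22 ± 0.2 (adjusted p = 6.72e-07) and reached a signal of 1027 ± 209. Further large rises were seen for AT5G45570 (4.95), the pseudogene AT2G04000 (4.76), AT5G07570 (4.47), AT1G59930 (4.45), AT5G41660 (4.36) and the pseudogene AT2G04770 (4.19). AT2G04000, AT1G59930 and AT2G04770 were read from probe sets whose suffix marks them as shared between related sequences. Their rises may therefore not belong to these loci alone. Among the falls, the pseudogene AT4G16870 went from 103.5 ± 19.0 to 16.2 ± 4.63, a log2 difference of -2.42 ± 0.25 (adjusted p = 0.000611). AT4G21870 (-1.77), AT4G16563 (-1.45), AT4G38225 (-1.17), the defensin-like gene LCR68 (-1.17), AT1G66180 (-1.04), AT2G36950 (-0.94), AT5G65660 (-0.85), the sucrose-phosphate synthase gene ATSPS4F (-0.71) and AT2G25870 (-0.67) were also lower. The rises named here kept their call whichever single array was left out, but several falls did not. The calls of AT2G25870, AT5G65660, AT4G21870, ATSPS4F, AT4G16563 and AT1G66180 were lost in 8, 6, 5, 5, 4 and 3 of 9 such fits: 6 falls lost their call without null mutant 1, 6 without null mutant 3, 5 without double transformant 3, 4 without double transformant 2, 3 each without double transformant 1, substitution array 2 or substitution array 3, and 1 without substitution array 1. Their log2 differences stayed negative in all 9 fits, each of which had fewer arrays, between -0.77 and -0.57 for AT2G25870, -0.94 and -0.69 for AT5G65660, -2.18 and -1.45 for AT4G21870, -0.81 and -0.65 for ATSPS4F, -1.76 and -1.14 for AT4G16563, and -1.17 and -0.79 for AT1G66180.

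Of 22746 probe sets, 173 differed between the null mutant and the double transformant, 150 higher and 23 lower, so that 86.7% of the calls were rises. Of these, 93 rises and 11 falls belonged to probe sets with a single named gene. A change of at least 2-fold was reached by 124 of the rises and 13 of the falls, and 19 rises exceeded a log2 difference of 3. The 3 arrays of each group did not overlap for 13.7% of probe sets, against 10% by chance. The count depended on single arrays: it was 73 without null mutant 1, 339 without null mutant 2 (70.5% rises), 100 without null mutant 3, 95 without double transformant 2 and 97 without double transformant 3. It was 57 without double transformant 3 and null mutant 3 together, 58 with only the 6 arrays of these groups in the fit and 7 with an unmoderated test.

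**Figure D1:**
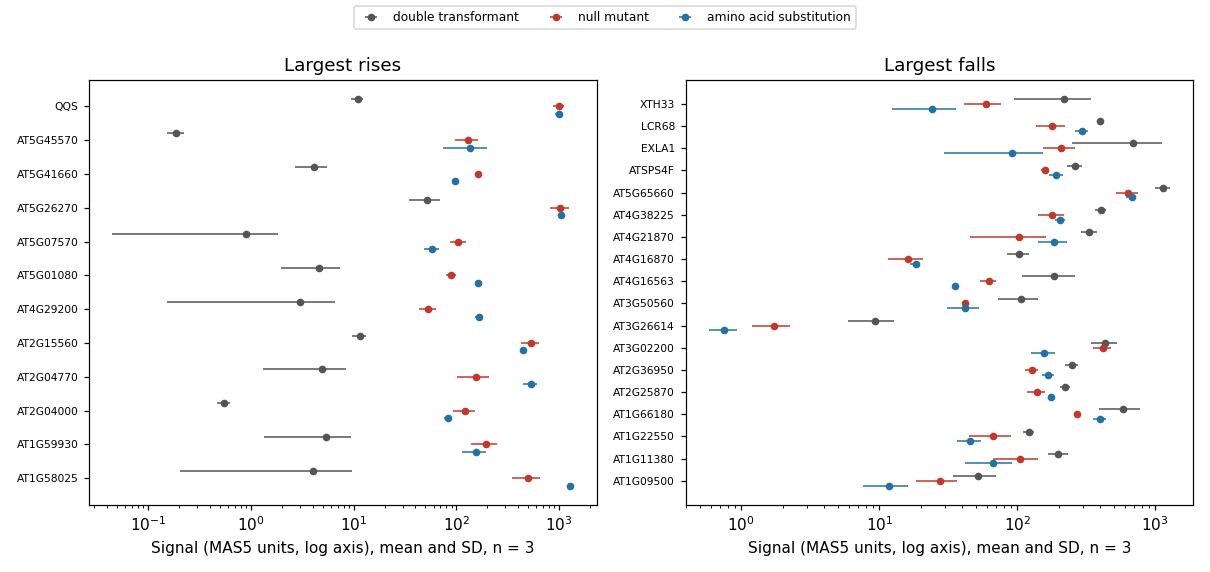
Mean signal with SD (n = 3 arrays per group, logarithmic horizontal axis, MAS5 units) of the genes with the largest rises and falls in either mutant group. Lower bars are shortened where the SD comes close to or exceeds the mean; QQS lies near 991 in the null mutant and near 994 in the substitution group, against 10.9 in the double transformant.

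The second comparison put the amino acid substitution mutant against the same reference. AT1G58025 rose from 4.06 ± 5.6 to 1287 ± 96.1 (SD, n = 3), a log2 difference of 7.52 ± 0.36 (limma adjusted p = 8.26e-07). QQS reached 994 ± 79.2, a log2 difference of 6.06 ± 0.13 (adjusted p = 3.19e-10). The pseudogene AT2G04770 rose by 5.98, AT5G45570 by 4.97, AT2G15560 by 4.85, AT4G29200 by 4.71, AT5G01080 by 4.29, AT5G26270 by 4.26, the pseudogene AT2G04000 by 4.23 and AT1G59930 by 4.14. The rises of AT2G04770, AT2G04000 and AT1G59930 again rest on probe sets marked as shared between related sequences. The largest falls were those of a pair of genes for cell wall proteins. XTH33, a xyloglucan endotransglucosylase gene, differed by -2.89 ± 0.43 (adjusted p = 0.0126) and EXLA1, an expansin-like gene, by -2.85 ± 0.47 (adjusted p = 0.0221). Both varied widely in the double transformant, where EXLA1 was at 686 ± 436 and XTH33 at 220 ± 125. AT4G16870 (-2.25), AT4G16563 (-2.18), AT1G09500 (-1.80), AT1G11380 (-1.56), the pseudogene AT3G26614 (-1.46), AT3G02200 (-1.45), AT1G22550 (-1.35) and AT3G50560 (-1.25) followed. The rises kept their call whichever single array was left out. The adjusted p of XTH33 and EXLA1 was 0.0597 and 0.0828 without double transformant 2, 0.0748 and 0.096 without double transformant 3, 0.0754 and 0.114 without substitution array 1, and 0.0745 and 0.113 without substitution array 2. AT3G26614 and AT3G50560 lost their call in 8 of 9 such fits, and AT1G09500, AT1G11380 and AT1G22550 in 5. Of the falls named, 7 were lost without each of these 4 arrays, 4 without substitution array 3, 2 each without double transformant 1, null mutant 1 or null mutant 2, and 1 without null mutant 3. The log2 differences stayed negative in all 9 fits, between -3.40 and -2.48 for XTH33, -3.35 and -2.37 for EXLA1, -1.58 and -1.26 for AT3G26614, and -1.47 and -1.02 for AT3G50560.

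In this comparison 170 probe sets were called, 141 higher and 29 lower (82.9% rises), of which 96 rises and 17 falls had a single named gene. At least 2-fold changes made up 111 of the rises and 16 of the falls. The arrays of both groups did not overlap for 19.2% of probe sets, against 10% by chance. The count was 52, 46 and 78 without substitution arrays 1, 2 and 3 in turn, 55 without double transformant 2 and 71 without double transformant 3. It was 370 without the 3 arrays whose titles end in rpt, with 47.3% of calls higher, 73 without double transformant 3 and null mutant 3 together, and 16 with an unmoderated test. Centring each array on its median left 124 calls.

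Of the 397 members of 20 gene lists fixed before the data were examined, 56 had a probe set of their own in the annotation used here, and 11 lists with at least 3 such members were tested. In the list of abscisic acid, drought and cold response, 1 of 3 members was called in the null mutant. COR15A, which encodes a cold-induced chloroplast protein, rose by 2.78 ± 0.47 (adjusted p = 0.0187), with arrays that spread widely (1435 ± 1070, SD, n = 3). Its adjusted p was 0.0625 without double transformant 1, 0.0967 without double transformant 3 and 0.0764 without null mutant 3, with log2 differences between 2.20 and 3.38 over the 9 fits without a single array. The dehydrin gene LTI30 differed by 2.37 ± 0.49 (adjusted p = 0.0535) and COR47 by 0.24 ± 0.25. Adjusted over the list alone, 2 of the 3 were higher. The list was higher as a set (camera adjusted p = 0.00528), and this was not kept with an estimated correlation (adjusted p = 0.912 with an estimated correlation). In the substitution group its camera adjusted p was 0.709, with 2 members higher and 1 lower adjusted over the list alone.

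None of the other 10 lists passed in either mutant group. Among flowering time regulators, GI, which acts in the clock and in flowering, differed by 0.67 ± 0.15 in the null mutant (adjusted p = 0.0812) and 0.73 ± 0.15 in the substitution group (adjusted p = 0.0569), and the list's adjusted p was 0.709 and 0.281. Pollen and tapetum markers had medians of -0.136 and -0.592 (adjusted p = 0.281 in both). SHT differed by -1.22 ± 0.53 and -1.49 ± 0.53, and ANX2 by -1.01 ± 0.39 and -0.87 ± 0.39. The histone deacetylase list, with HDA7, HDA15 and LDL2 measured, had an adjusted p of 0.877 and 0.281. Adjusted p for the null mutant and the substitution group was 0.815 and 0.877 for leaf senescence, 0.709 and 0.963 for photosynthesis, 0.909 and 0.909 for heat shock, 0.81 and 0.328 for glucosinolate synthesis, 0.909 and 0.709 for anthocyanin synthesis, 0.907 and 0.877 for jasmonate and ethylene response, and 0.909 and 0.909 for acetate and ethanol fermentation. WRKY53, a senescence regulator, differed by 1.84 ± 0.47 in the substitution group (adjusted p = 0.12). In lists too small to test, QQS was called, while PAP85, a seed storage gene, differed by 1.98 ± 0.55 and 2.37 ± 0.55 (adjusted p = 0.168 and 0.0901). DME, UFO, SPT, EXPA7, EXPA18, AUR1, CLV3 and PHV did not pass in either group.

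Both mutant groups shared many calls. Of 261 probe sets called in either, 82 were called in both in the same direction, 75 higher and 7 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.93 rises and 0.029 falls. Both comparisons used the same double transformant arrays, and in 100 simulated sets of unchanged mutant groups the largest shared count was 1. The log2 differences correlated at 0.675 over all probe sets, which are not independent replicates, against a simulated mean of 0.5. Their covariance was 0.144 against a simulated 0.0537. The 3 control arrays were not split, since one part would hold a single array. The simulated groups share the controls but hold no real effects, and part of the excess over independent lists may come from the shared controls. The shared count was 34 to 95 when single arrays were left out, the lowest without substitution array 2. Of 75 rises called in the null mutant only, 68 were above the double transformant in the substitution group. Of 66 called in the substitution group only, 66 were above it in the null mutant. Shared controls favour the same sign. By the direct contrast, 8 of the 261 differed between the mutant groups. A call in 1 group alone therefore does not show a difference between them.

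**Figure D2:**
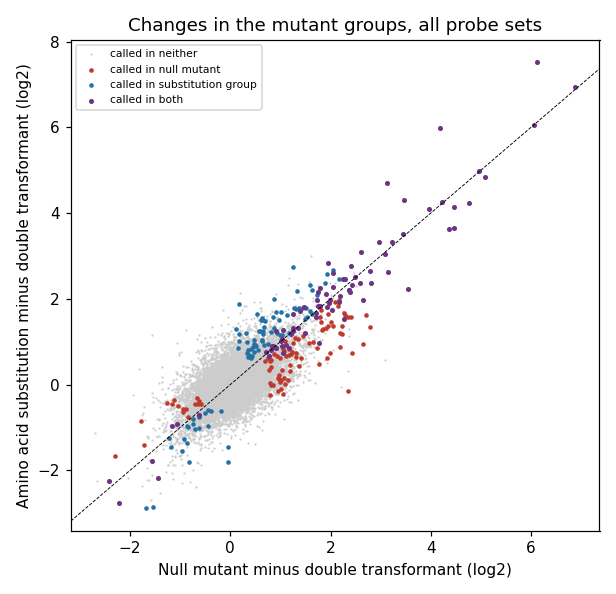
Each point is a probe set, with the log2 difference of the null mutant from the double transformant on the horizontal axis and that of the substitution group on the vertical axis. Colours mark calls at adjusted p under 0.05, and the dashed line marks equal differences. The 82 shared calls have the same sign in both groups, and some lie off the line, such as AT2G04770 (4.19 and 5.98).

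Loci annotated as pseudogenes, a class in which the annotation also places transposable element genes, were frequent among the rises. In the null mutant 26 of 923 measured pseudogene loci were higher (2.82%), against 66 of 12363 other loci (0.534%), an odds ratio of 5.4 (Fisher's exact test, two-sided, adjusted p = 1.48e-09). In the substitution group 23 were higher (2.49% against 0.59%, odds ratio 4.3, adjusted p = 2.28e-07). Loci matched on their double transformant level would give 9.45 and 9.07 (permutation test matched on level, p = 1e-04 in both, the smallest that 10000 draws can give). Both kinds of test treat loci read from the same arrays as independent, so their p-values may be too small. They do not measure the spread between arrays. The raised loci differed by a median of 2.16 and 2.31 on the log2 scale, and 14 were raised in both groups. Among probe sets with the plain suffix, which leaves out sets marked as shared between related sequences, 15 and 10 pseudogene loci were higher. The odds ratios were 3.92 (95% interval 2.06 to 6.99) and 2.34 (1.07 to 4.58). Falls numbered 1 and 2 over all probe sets, against 0.00602 and 0.102 expected (permutation test matched on level, p = 0.006 and 0.002). These falls were AT4G16870, counted in both groups against the same double transformant arrays, and AT3G26614 in the substitution group. The call of AT3G26614 was lost in 8 of 9 fits without a single array. So few loci cannot show whether the excess extends to falls (Fisher's exact test, adjusted p = 0.547 and 0.409). The counts depended on single arrays. In the null mutant 8 loci were higher without null mutant 1, 13 without null mutant 3, 12, 9 and 16 without double transformant 1, 2 and 3, and 17, 14 and 14 without substitution arrays 1, 2 and 3. In the substitution group 8, 6 and 8 were higher without its own arrays 1, 2 and 3, and 15, 8 and 14 without double transformant 1, 2 and 3. Over the 9 fits without a single array the odds ratio ran from 2.57 to 5.17 in the null mutant and from 2.47 to 5.27 in the substitution group, with lower bounds of 1.26 and 1.04 at the least. Without the 3 arrays whose titles end in rpt, 5 and 10 loci were higher, with odds ratios of 2.17 (0.656 to 5.64) and 1.51 (0.698 to 2.92), so that the excess no longer passed. At adjusted p under 0.01 they were 2.88 (0.973 to 7.12) and 3.25 (1.2 to 7.61), and without moderation 4.47 (0.085 to 55.7) and 2.68 (0.285 to 12.6). Without dim probe sets they were 53.4 and 51.8. That filter used the mean over all 9 arrays, so loci could pass it through the groups where they rose. As a class, all pseudogenes together had a median log2 difference of 0.112 in the null mutant (camera direction up, unadjusted p = 0.0235, adjusted p = 0.141) and 0.0104 in the substitution group (direction up, adjusted p = 0.322), against medians of 0.019 and -0.003 over all probe sets, and passed in neither.

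The third comparison put both mutants against each other and called 9 probe sets, 8 higher and 1 lower in the null mutant, 5 of them with a single named gene. AT3G02200 was higher in the null mutant by 1.41 ± 0.18 (limma adjusted p = 0.0259), at 418 ± 62.5 in the null mutant and 156 ± 30.6 in the substitution group (SD, n = 3). The double transformant was at 434.5 ± 90. From it the null mutant differed by -0.04 (limma adjusted p = 0.961) and the substitution group by -1.45 (adjusted p = 0.00396), so the difference was a fall in the substitution group. AT3G16670 was lower by -2.72 ± 0.38 (adjusted p = 0.0356). AT5G39590 (1.05 ± 0.11), AT5G39410 (0.95 ± 0.12) and AT5G40190 (0.86 ± 0.12) were higher in the null mutant, with adjusted p of 0.00678, 0.0259 and 0.033. These counts rested on few arrays: 0 probe sets were called without null mutant 3, without substitution array 1 or without substitution array 3, 48 without null mutant 2, of which 20 were higher and 28 lower, 14 without double transformant 1 (9 higher and 5 lower), 3 each without double transformant 2, double transformant 3 or null mutant 1, 4 without substitution array 2, and 0 without a variance trend. All 5 named genes lost their call without null mutant 3, substitution array 1 or substitution array 3, 4 of them without null mutant 1, double transformant 2 or double transformant 3, and 3 without substitution array 2. Their log2 differences kept their sign in all 9 fits, between 1.29 and 1.56 for AT3G02200 and between -3.25 and -2.42 for AT3G16670. Quantile normalization gave 8 higher and 0 lower, and centred medians 5 higher and 0 lower. At an unadjusted p under 0.05, 1447 probe sets were counted.

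AT5G39410, AT5G39590 and AT5G40190 lie in one stretch of chromosome 5. A search for runs of neighbouring genes, chosen after the values were seen and restricted to genes above the median level, found 16 such genes from AT5G39250 to AT5G40190, by gene order in the TAIR10.1 annotation. All 16 were higher in the null mutant than in the substitution group, by a median of 0.873 on the log2 scale (bootstrap 95% interval 0.779 to 1.04; permutation p = 0.000999 in 1000 shuffles of gene order, the smallest they can give). The run was also the best-scoring one in the comparison with the double transformant, where the median was 0.906 (0.799 to 1.15) and the same permutation gave p = 0.0569. Because the run was selected for its size, these medians may be too high. The bootstrap intervals of the run were drawn over its genes, so they do not measure the spread between arrays. With single arrays left out they ran from 0.832 to 0.929 against the substitution group and from 0.856 to 0.949 against the double transformant. Over all alternatives, 43 medians of the run stayed within 1 SD of the null mutant arrays from the main value, and 3 moved further. Of the 30 dimmer genes inside it, 21 were higher than in the substitution group, with a median of 0.445 (0.0574 to 0.607). The substitution group differed from the double transformant over the run by 0.0492 (-0.0704 to 0.217). Per array the median was 0.901, 0.903 and 1.03 in the null mutant and between -0.0142 and 0.0857 in the substitution group.

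**Figure D3:**
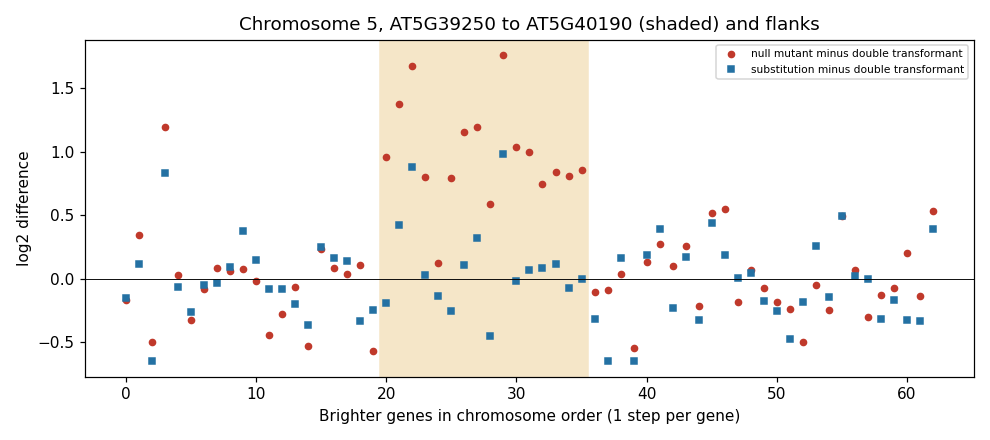
Log2 difference from the double transformant for genes above the median level, in chromosome order across the run from AT5G39250 to AT5G40190 (shaded) and its flanks. Null mutant values (circles) lie above 0 over the shaded run, with a median of 0.906, and substitution values (squares) have a median of 0.0492.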

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

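The tests of the chromosome 5 run, of the pseudogene rise and of shared controls were chosen after the results were seen; the splits of the arrays were planned beforehand. The null mutant and the substitution group differed by the direct contrast for AT3G02200 (1.41), AT5G39590 (1.05), AT5G39410 (0.95), AT5G40190 (0.86) and AT3G16670 (-2.72), as log2 difference of the null mutant from the substitution group. For AT3G02200 the difference from the double transformant was -0.04 in the null mutant and -1.45 in the substitution group. Of 64 control probe sets outside the comparisons, 0 differed in either mutant group by limma, with 1 and 3 at an unadjusted p under 0.05.

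The run of chromosome 5 genes was higher in the null mutant only. No shift of the whole chromosome was seen, as the other brighter genes had a median difference from the substitution group of 0.0195. This is no independent test of scaling. The arrays had been scaled to a common level, and the run was chosen for standing above other genes. A change shared by both HDA6 mutants is argued against by a median of 0.0492 (-0.0704 to 0.217) in the substitution group. Intervals in this paragraph were drawn over genes, not arrays. Per array the median lay between -0.0142 and 0.0857 in the substitution group and between 0.901 and 1.03 in the null mutant. The search against the double transformant, which uses no substitution array, gave the same run (permutation p = 0.0569). An extra copy of the segment in the null mutant line stays open. The 16 brighter genes, selected for their rise, shifted together, with an interquartile range 0.944 times that of other brighter genes and a median fold of 1.83 (1.72 to 2.05), but over all 46 genes the ratio was 1.94, the fold 1.54 (1.38 to 1.71) and 37 were higher, and of the 30 dimmer genes, whose differences the offset shrinks, 21 were higher. A regional effect of the null allele alone, and a difference of the line unrelated to HDA6, stay open, and DNA was not analysed here.

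Pseudogene loci were frequent among rises. Noise that depends on level alone is argued against as the whole cause, since 26 and 23 loci were higher against at most 20 and 21 in 10000 draws matched on level (permutation p = 1e-04 in both, the smallest they can give). Without the 3 rpt arrays the odds ratios were 2.17 (0.656 to 5.64) and 1.51 (0.698 to 2.92), so a contribution of those arrays stays open. Sets marked by suffix as shared are argued against as the whole cause by an odds ratio of at least 2.34 among plain probe sets. Its lower bound was 1.07 in the substitution group. There, 10 pseudogene loci with plain probe sets were higher against 5.27 expected, with draws reaching 14 (permutation test matched on level, p = 0.03). Whether plain probe sets also bind related sequences was not tested. The share of measured pseudogene loci that were higher was 2.04% among plain probe sets against 2.82% among all in the null mutant. It was 1.36% against 2.49% in the substitution group, so part of the excess may come from the marked sets. Release of silencing in both HDA6 mutants stays among the open explanations, as untested.

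The overlap of 82 probe sets was above the 1 that simulated shared controls gave at most. The simulation drew independent noise for each probe set around unchanged levels, so few calls could arise in it. Deviations that run over a whole control array were not modelled, so it cannot exclude that shared controls added to the overlap. Of 100 drawn splits of the 9 arrays into 3 groups, 1 gave as large an overlap, the real one. This argues against random spread between single arrays as the source of the parting of double transformant from mutant arrays, and against nothing further. The splits treat the arrays as independent. The labels do not say that they came from separate cultures, so a chance difference between cultures cannot be excluded. The highest other value was 78, from the only drawn split that kept the 3 double transformant arrays as controls but divided the mutant arrays otherwise, and the highest of the rest was 5. With 10 splits of 6 arrays no share under 0.05 can be reached. The real count was 173 against at most 5 in the other splits for the null mutant (1 of 10 as large), and 170 against 0 for the substitution group (1 of 10). Between the mutants 2 of 10 splits gave as many as the real 9, the other with 18.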

How the results depend on the processing

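All values here are counts of calls unless a p is named. An offset of 8 times c, leaving out double transformant 3 and null mutant 3 together, and plain probe sets only were chosen after the data were seen. Directions were compared only where a result passed its threshold, and 0 of the named genes reversed. Of 46 calls of named genes, 21 were lost without double transformant 3 and null mutant 3, 19 without a variance trend, 16 without the rpt arrays, 13 with 6 arrays in the fit, 6 with either block, 4 with the robust prior, 3 with centred medians or an offset of 8 times c, and 1 or 2 with no offset, an offset of 2 times c, quantile normalization or array weights. With single arrays left out 2 to 17 were lost, the most without double transformant 3 and the fewest without null mutant 2, and 0 of 45 were lost without dim probe sets. Pseudogene loci higher numbered 8 to 24 in the null mutant (26) and 6 to 28 in the substitution group (23) with single arrays left out, 12 in both without dim probe sets, 5 and 10 without the rpt arrays, 6 and 7 at adjusted p under 0.01, 1 and 2 without moderation, 6 in the null mutant with 6 arrays, 12 in the null mutant without double transformant 3 and null mutant 3, and 42 in the substitution group with array weights. For the null mutant against the double transformant (173), the count was 113 without a variance trend, 61 without the rpt arrays, 58 with 6 arrays in the fit, 57 without double transformant 3 and null mutant 3, 59 at adjusted p under 0.01 and 7 without moderation, and 73 to 339 with single arrays left out. For the substitution group (170) it was 88 without a variance trend, 373 with array weights, 370 without the rpt arrays, 73 without double transformant 3 and null mutant 3, 47 at adjusted p under 0.01 and 16 without moderation, and 46 to 212 with single arrays left out. Between the mutants (9) it was 5 with centred medians, 5 with an rpt block, 18 without the rpt arrays, 4 with 6 arrays, 3 at adjusted p under 0.01, 0 without a variance trend, without double transformant 3 and null mutant 3 or without moderation, and 0 to 48 with single arrays left out. The overlap (82) was 53 without the rpt arrays, 37 with 6 arrays, 40 without double transformant 3 and null mutant 3, 33 at adjusted p under 0.01 and 5 without moderation, and 34 to 95 with single arrays left out. Many of these fits had fewer arrays or a stricter test, but some with fewer arrays gave more calls, such as 339 and 370. What caused the changes was not tested.

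With a replicate block the substitution group had 321 calls. Same-numbered arrays correlated between -0.0409 and 0.154, and 4 of 9 arrays correlated best with their own number. No pairing by number was seen in these values, but with 3 arrays per group it cannot be excluded. The abscisic acid list in the null mutant had an adjusted p of 0.0793 without double transformant 3 and null mutant 3, 0.912 with an estimated correlation and 0.548 with fry. Pollen and tapetum markers had an adjusted p of 0.0189 to 0.672 in the null mutant and 0.0189 to 0.581 in the substitution group with single arrays left out, the lowest without double transformant 2. The robust prior was not run for lists. Signals near background limit what can be said of dim probe sets.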

Other observations

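The families below and the neighbourhood test were chosen after the data were seen. Among 21 symbol families with at least 10 measured members, tested in both mutant groups (42 tests), the EXPA family of expansins, which loosen cell walls, was higher in the substitution group (camera adjusted p = 0.0286), with 7 of 10 members above the double transformant. This call was not kept with an estimated correlation (adjusted p = 0.439 with an estimated correlation). EXPA8 differed by 1.63 ± 0.21 (limma adjusted p = 0.00459) and EXPA9 by 1.57 ± 0.2 (adjusted p = 0.00414); EXPA8 was also higher in the null mutant, by 1.26 ± 0.21. The family's adjusted p was 0.0692 after quantile normalization and 0.165 without double transformant 3, and the call was lost in 11 of 24 alternatives.

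If raised genes lay in silenced regions, protein-coding genes called higher might have more pseudogenes among the 20 annotated genes on each side than genes of the same level. In the null mutant the share was 11.3% against 5.26% for matched genes (57 genes, adjusted p = 0.0064), and in the substitution group 8.32% against 5.17% (71 genes, adjusted p = 0.074). Neighbouring genes share flanking genes, so one region can count several times and these p-values may be too small. Within the chromosome 5 run 8 genes were called higher in the null mutant and 1 in the substitution group. The test was not repeated without the run. The hypothesis is left undecided, because only the null mutant passed and the difference between the groups was not tested.

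The 3' to 5' signal ratio of the GAPDH control ran from 1.38 to 2.15 over the arrays, highest in double transformant 3 and next in null mutant 3 (1.95), and that of the ubiquitin control from 3.19 to 3.75. The 25S ribosomal RNA control ranged from 501 to 4247, highest in substitution array 3 and lowest in double transformant 2.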
